A study of Rattus norvegicus with 8 samples.

How the data were processed

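The deposited files are filtered count matrices of unique molecular identifiers (UMIs) per gene and cell barcode, 1 matrix for each of 8 libraries. Per the submitters' processing notes, the counts were made with Cell Ranger 6.1.1 on the rat genome Rnor_6.0, and no reads were used here. Per the labels' protocols, gray and white matter were dissected under a microscope, digested with papain and deoxyribonuclease at 37 °C for 30 minutes, cleared of myelin debris with Percoll and enriched with CD11b/c beads, and each library mixed cells of 3 rats. Gene symbols and identifiers are those of the matrices, which held 32623 genes. No genome coordinates were used.

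The design, the gene lists, the cell type markers, the comparisons and the alternatives were chosen before the data were examined, apart from the additions named below. Gray and white matter libraries of the same condition and time were taken to come from the same 3 rats, which the labels do not state. This gave 4 pools of 2 libraries. As a check, deviations of 5279 genes from the mean of their region were correlated between libraries, and the correlation within pools was 0.679 (CCH, 4 weeks), 0.384 (sham, 4 weeks), 0.0745 (CCH, 8 weeks) and -0.107 (sham, 8 weeks). At 8 weeks each gray matter library correlated best with the white matter library of the other condition, so the pairing is uncertain there.

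Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. A laxer filter of 200 genes, 500 UMIs and 20% was an alternative. Scrublet called 0% to 0.0437% of cells per library as doublets, so the doublet caller did not work on these libraries, and removing the top 5% of scores was added as an alternative after the data were seen. The kept cells were clustered with scanpy (2000 variable genes, 30 principal components, 15 neighbors, Leiden resolution 1, with 0.5 as an alternative). Clusters were named from 18 marker lists by mean log2 fold over the mean of the other clusters with 20 CPM added, with at least 3 markers detected. A class other than microglia was named only where microglial markers were on average lower than in the other clusters. Clusters of low depth with no marker of their class among the top 10 genes stayed unnamed, such as 767 cells with a median of 1231 UMIs and a microglial score of 0.797. The naming thresholds were set after the clusters were seen. Of 25 clusters, 13 were named microglia-like and 5 stayed unnamed. The 8 named classes were microglia, border macrophage, monocyte, T, NK and B cells, oligodendrocyte (50 cells) and astrocyte (18 cells), and 10 marker lists named no cluster (dendritic cells, neutrophils, oligodendrocyte precursors, neurons, endothelial, mural, fibroblast, ependymal or choroid plexus, erythroid and mast cells). An unnamed cluster of 193 cells, led by S100a9 and S100a8, did carry neutrophil markers (mean log2 fold 2.90, 8 detected). Its microglial markers were not lower than in the other clusters (0.28), so the rule left it unnamed.

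UMIs of microglia-like cells were summed per library, and 12403 genes passing edgeR's filterByExpr were tested with TMM scaling (factors 0.931 to 1.11) and the robust quasi-likelihood F test. Region was tested with a pool block (3 residual degrees of freedom). Condition and time were tested in an additive model of the 8 libraries (4 residual degrees of freedom), whose p is too small where the 2 libraries of a pool deviate together, and the interaction within pools (2 residual degrees of freedom). P-values were adjusted over all genes by Benjamini and Hochberg at 0.05. Comparisons of single libraries have values only. Shares of cells were compared by exact sign-flip tests over 4 pairs.

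The 20 fixed gene lists were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists. List tests for time and interaction were added after the data were seen. List symbols absent from the matrices or below the filter, such as Gapdh and Cd36, were not analysed here.

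The rule for naming genes took, per comparison, up to 10 passing genes per direction with the largest change, a mean of at least 20 CPM and the same direction in 4 of 4 pairs, and where none did, the 5 per direction with the smallest unadjusted p that met the other conditions, leaving out unnamed gene models, ribosomal and mitochondrial genes. For the interaction, the same direction meant that white minus gray in both CCH pools lay outside the values of both sham pools. The rule added up to 4 members per list with the smallest p and 8 fixed genes (Apoe, Spp1, Cd74, P2ry12, Tmem119, Il1b, Lpl and Trem2). Among all genes, 17.1% moved the same way in 4 of 4 pairs for region, 9.45% for condition and 23.7% for time. By chance 12.5% would do so if the 4 pairs were independent. For condition and time the gray and white matter pairs share pools. Where the libraries of a pool deviate together, the chance share is higher than 12.5%, and it was not computed. For the interaction the share was 46.3%, with 33.3% by chance.

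Intervals of shares are exact binomial and those of CPM exact Poisson, and both cover counting error only. The floor of a library is the CPM of 3 counts. In a self-test on counts simulated from the real means, library sizes and dispersions, 200 genes were changed by log2 fold changes of 1, 2 or 3, and recovery was 68.3%, 93.0% and 98.5% for region, 59.7%, 98.4% and 100% for condition, 70.1%, 98.4% and 98.5% for time and 14.1%, 65.7% and 82.4% for the interaction. False calls were 21 of 193, 12 of 177, 17 of 190 and 21 of 130, above the nominal 5%. Simulated libraries were drawn independently around a common mean, with no deviation shared within a pool. Recovery for condition and time was therefore not tested where the libraries of a pool deviate together. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.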

Results

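Chronic cerebral hypoperfusion (CCH) is a lasting shortage of blood flow to the brain. In these rats it followed occlusion of both common carotid arteries, a procedure used to model vascular dementia, and sham rats served as controls. Animals were male Sprague-Dawley rats, 8 weeks old when obtained. Brains were taken 4 or 8 weeks after surgery and dissected into gray matter, rich in neuronal cell bodies, and white matter, rich in myelinated axons. Cells were enriched with magnetic beads against CD11b/c, integrins carried by microglia and other myeloid cells, and were profiled by droplet-based single-cell RNA sequencing with unique molecular identifiers (UMIs). Each of the 8 combinations of condition, region and time was 1 library pooled from 3 rats, so no combination had a replicate, and tests rested on the factorial of 8 libraries.

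The libraries held 5787 to 8939 barcodes. At 4 weeks their totals were 51323031 UMIs for CCH gray, 53670508 for CCH white, 43729900 for sham gray and 51378269 for sham white matter. At 8 weeks they were 54963745, 52996277, 59661099 and 43696051 in the same order. Of 62546 barcodes, 53883 (86.1%) passed the cell filter, and 49048 of these fell in clusters named microglia-like. Microglia-like cells had median depths of 5028 to 5800.5 UMIs per cell and sums of 38663613 to 48564250 UMIs per library. A gene with 0 UMIs in such a sum was below 0.0618 to 0.0776 counts per 1000000 (CPM), the level of 3 counts.

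The first comparison asked which cells each fraction held. Microglia-like cells, made up 94.5% of cells in white and 87.4% in gray matter, a difference of 7.14 points ± 5.0 (SD, 4 within-pool pairs, higher in 4 of 4). Border macrophage-like cells, led by Mrc1, F13a1 and Pf4 and known to reside at the meninges and vessels, made up 0.286% in white and 5.45% in gray matter, a difference of -5.17 points ± 3.80. Their gray matter shares were 1.83% (exact binomial 95% interval 1.53 to 2.18) in CCH and 2.66% (2.30 to 3.07) in sham rats at 4 weeks. At 8 weeks they were 8.86% (8.10 to 9.66) in CCH and 8.45% in sham rats. Lymphocyte-like cells (T, NK and B cells) made up 1.2% in white and 2.63% in gray matter, and 452 of the gray matter cells came from the sham library at 8 weeks, where they were 6.25%. In the other gray matter libraries they were 0.342% to 2.14%, and in the white matter libraries 0.746% to 1.62%, so the difference rests largely on that library. CCH and sham libraries differed little in microglia-like cells, with means of 91.4% and 90.4% and a difference of 1.04 points ± 2.50, higher in CCH in 3 of 4 pairs. Oligodendrocyte-like cells numbered 50, all from white matter.

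With 4 pairs, the smallest 2-sided p of the exact sign-flip test was 0.125. That p was reached for microglia-like and border macrophage-like cells between regions (exact p = 0.125 each), while the exact p was 0.5 for lymphocyte-like cells between regions and 0.5 for microglia-like cells between conditions. The magnetic enrichment can itself set such shares, and under a laxer cell filter microglia-like cells were higher in white matter in 3 of 4 pairs (exact p = 0.25). The difference between conditions was 2.52 points under that filter and 0.353 at a coarser clustering.

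**Figure D1:**
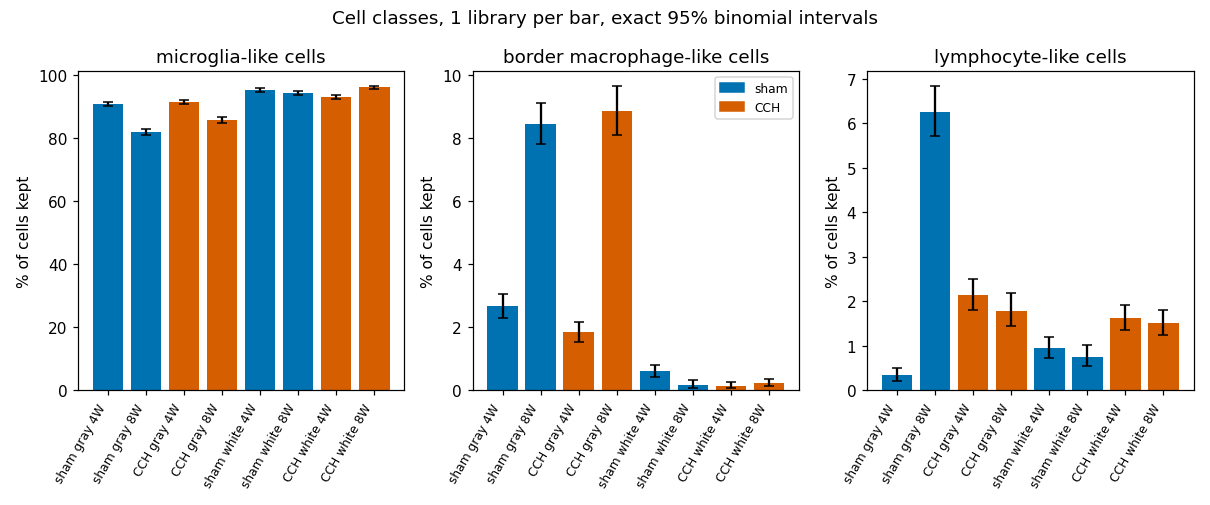
Shares of kept cells (vertical axis, percent) that were microglia-like, border macrophage-like or lymphocyte-like, 1 bar per library, with exact 95% binomial intervals. Border macrophage-like cells stood at 8.86% and 8.45% in the gray matter libraries at 8 weeks and below 0.6% in every white matter library.

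Microglia-like cells of different libraries fell in different clusters, and this stands beside every comparison that follows. In sham rats, 75.5% of gray matter microglia at 4 weeks were in cluster 4 (led by Ier3 and Il6), 75.7% of white matter microglia at 4 weeks in cluster 10 (Egr2, Plk2), 63.4% of gray matter microglia at 8 weeks in cluster 13 (C3, Cd74, RT1-Ba) and 48.8% of white matter microglia at 8 weeks in cluster 5 (Siglec5, P2ry12). At this clustering the largest cluster of a library held 29.0% to 45.1% of CCH microglia and 48.8% to 75.7% of sham microglia. In CCH at 4 weeks 44.8% of the gray matter cells were in cluster 0 (Spp1, Ccl12), and in white matter 29.0% were in cluster 2 (Trem2, Cst3) and 23.6% in cluster 1 (Gpnmb, Spp1, Ctsd). At 8 weeks cluster 7 (Fam111a, Hmox1) held 45.1% in gray and 36.7% in white matter, where cluster 8 (Atf3, Hspb1) held another 30.6%.

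Between regions, microglia of white matter carried more RNA of cholesterol synthesis genes. Of 18 members, 17 were higher in white matter, with a median log2 fold change of 0.47. Squalene epoxidase Sqle stood at 0.82 ± 0.10 (SE; 4 pairs), lanosterol demethylase Cyp51 at 0.74 ± 0.09 and Sc5d, which acts late in the pathway, at 0.62 ± 0.08, each higher in 4 of 4 pairs. Sqle stood at 25.3 CPM in gray and 45.1 in white matter of CCH rats at 4 weeks, and at 33.3 and 64.8 in sham rats. Adjusted over the list alone, 15 members rose, while over all genes none passed (adjusted p = 0.0967 for Sqle, Cyp51 and Sc5d, edgeR's quasi-likelihood test). The list differed from other genes by camera (adjusted p = 8.74e-38), a call lost with an estimated correlation (p = 0.007, adjusted p = 0.14).

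Over all 12403 genes tested, 3 rose in white matter and none fell. They were Pdlim1 (ENSRNOG00000016166), a PDZ and LIM domain protein of the cytoskeleton (log2 fold change 1.92 ± 0.13, adjusted p = 0.00839), Apod (ENSRNOG00000048273), a lipid-binding apolipoprotein (3.68 ± 0.32, adjusted p = 0.0272), and the myelin gene Mobp (ENSRNOG00000018700; 3.55 ± 0.32, adjusted p = 0.0272). All 3 lie below the mean of 20 CPM set for naming genes and were chosen after their values were seen. Pdlim1 stood at 2.74 CPM in gray and 12.4 in white matter of CCH rats at 4 weeks. Apod and Mobp stood at 15.1 and 5.58 CPM in microglia of CCH white matter at 4 weeks, and lymphocyte-like cells of that library, which should lack them, held 12.46 CPM (exact Poisson 95% interval 5.97 to 22.9) and 7.48 CPM (2.74 to 16.3). At an unadjusted p under 0.05 stood 1050 genes, 632 higher and 418 lower. The call of 3 genes became 147 with DESeq2, 0 without the sham 4-week pool, 174 without the sham 8-week pool and 0 without the pool block.

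Genes of the naming rule that did not pass included Cd4, a co-receptor of T cells that rat macrophages also carry (0.83 ± 0.12, adjusted p = 0.0967), and Pik3ip1, an inhibitor of PI3 kinase (1.05 ± 0.16, adjusted p = 0.101). Lower in white matter were Cp, the copper ferroxidase ceruloplasmin (-0.64 ± 0.12), and Sept1 (-0.45 ± 0.08), both at adjusted p = 0.154, Fkbp10 (-0.42 ± 0.09), Hist1h2an (-0.42 ± 0.10) and Plscr3 (-0.30 ± 0.08). Homeostatic microglial genes differed little, with P2ry12 at 0.14 ± 0.18 and Tmem119 at 0.16 ± 0.15. Mrc1, a border macrophage marker, stood at -2.57 ± 0.71 (adjusted p = 0.488), beside the larger share of border macrophage-like cells in gray matter.

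Stress and cytokine genes also stood higher in white matter microglia, mainly in the sham 4-week and CCH 8-week pools. All 25 immediate early and dissociation genes were higher (median 0.44), among them Klf6 (0.68 ± 0.15) and the chaperone Hsph1 (0.84 ± 0.19), the 2 that rose when adjusted over the list alone. Of 25 inflammatory genes 19 were higher (median 0.57), with the chemokines Cxcl1 at 1.28 ± 0.28 and Ccl2 at 0.76 ± 0.19, and of 18 hypoxia genes 14 were higher (median 0.19), with Vegfa at 0.88 ± 0.26 and Adm at 0.75 ± 0.23. Damage-associated genes, a set known to rise in microglia near lesions, were higher in 15 of 21 cases (median 0.10, mean 0.70), with Lgals3 at 2.51 ± 0.81, Fabp5 at 1.74 ± 0.53 and Ctsd at 0.48 ± 0.15. Spp1 stood at 1.95 ± 0.78, Il1b at 0.65 ± 0.85, Lpl at 0.18 ± 0.70, and Apoe (-0.57 ± 0.21) and Trem2 (-0.17 ± 0.17) were lower. Over all genes none of these genes passed. In the sham 4-week and CCH 8-week pools the pair medians were 0.82 and 1.02 for immediate early and 0.998 and 0.53 for inflammatory genes. In the sham 8-week and CCH 4-week pools they were 0.21 and 0.06 for immediate early and 0.05 and 0.05 for inflammatory genes. By mean log2 CPM both lists were lower in white matter of the sham 8-week pool (8.97 against 9.06, and 5.70 against 5.81).

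Lower in white matter were all 23 nuclear genes of oxidative phosphorylation (median -0.22; Uqcrq -0.29 ± 0.09, Atp5mc3 -0.38 ± 0.16), 18 of 20 cell cycle genes (median -0.27; Mcm7 -0.29 ± 0.10) and 23 of 30 interferon genes (median -0.20). By camera the adjusted p was 5.39e-11 for immediate early, 1.25e-05 for inflammatory, 0.00253 for hypoxia, 0.0466 for damage-associated, 2.07e-07 for oxidative phosphorylation, 5.27e-04 for cell cycle and 0.0437 for interferon genes. With an estimated correlation these calls were lost (adjusted p = 0.711, 0.711, 0.357, 0.797, 0.764, 0.797 and 0.797). Without the CCH 4-week pool the calls of cell cycle (median -0.04, adjusted p = 0.606) and damage-associated genes (0.05, adjusted p = 0.447) ended. The damage-associated call also ended without the CCH 8-week pool (0.16, adjusted p = 0.322), and without the sham 8-week pool the interferon median turned to 0.08 (adjusted p = 0.231). Calls held but medians moved for damage-associated genes without the sham 4-week pool (0.32) or the sham 8-week pool (0.21) and with library size alone (0.18), and for inflammatory genes without the sham 4-week pool (0.26) or the CCH 8-week pool (0.30). They moved likewise for immediate early (0.18) and interferon genes (-0.37) without the CCH 8-week pool, for oxidative phosphorylation genes without the sham 8-week pool (-0.11), and for interferon genes with library size alone (-0.13). With the immediate early level of each library as a covariate, the inflammatory median turned to -0.05 (adjusted p = 0.869) and the damage-associated call ended (0.35, adjusted p = 0.302).

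The 12 other lists did not pass in the region comparison. Their medians were 0.03 for homeostatic (adjusted p = 0.521), -0.09 for lysosomal (0.107), -0.12 for MHC class I (0.0596), -0.18 for complement (0.107), -0.05 for cholesterol efflux (0.521), -0.05 for glycolysis (0.643), -0.0016 for antioxidant and iron handling (0.922), -0.13 for phagocytic receptors (0.107), -0.06 for S100, annexin and galectin genes (0.922), 0.0072 for alternative activation (0.531) and -0.14 for mitochondrially encoded transcripts (0.163). MHC class II genes had a median of 0.67 and a mean of 0.42, while camera's direction was down (adjusted p = 0.997). Their pair medians were 1.01, 1.31 and 1.64, and -2.67 in the sham pool at 8 weeks, whose gray matter library held Cd74 at 6607 CPM. Means differed in sign from medians for glycolysis (0.0076), antioxidant (0.04), S100 (0.18) and alternative activation genes (-0.30).

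The second comparison asked what CCH did to microglia, with CCH and sham libraries matched by region and time. Cholesterol synthesis genes stood lower in CCH, in 16 of 18 members, with a median log2 fold change of -0.33. At 4 and 8 weeks the pair medians were -0.05 and -0.29 in gray and -0.28 and -0.45 in white matter, so gray matter at 4 weeks differed little. Sqle was at -0.60 ± 0.11 (SE of the additive fit of 8 libraries), Cyp51 at -0.43 ± 0.09 and Fdft1, squalene synthase, at -0.34 ± 0.08, each lower in 4 of 4 pairs. These SEs are too small where the 2 libraries of a pool deviate together. Adjusted over the list alone, 6 members fell, among them Sqle, Insig1, Fdft1 and Cyp51, and over all genes none did (adjusted p = 0.752 for Sqle, Cyp51 and Fdft1, edgeR's quasi-likelihood test). Camera gave adjusted p = 2.10e-16, and the call was lost with an estimated correlation (p = 0.0122, adjusted p = 0.244). The list median was -0.18 without the CCH 8-week pool (adjusted p = 2.07e-04) and -0.19 without the sham 8-week pool (adjusted p = 3.71e-05).

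Damage-associated genes were higher in CCH in 18 of 21 cases (median 0.22). Among them were the secreted glycoprotein Spp1 (3.13 ± 0.75), the tetraspanin Cd63 (0.56 ± 0.21), the protease Ctsd (0.37 ± 0.14) and the lipid carrier Apoe (0.39 ± 0.21), each higher in 4 of 4 pairs and none passing over all genes or over the list alone (adjusted p = 0.983 each over all genes). Spp1 had 0 UMIs in the sham gray matter library at 8 weeks, so its fitted fold change depends on the prior count. Trem2 stood at 0.27 ± 0.17 and Lpl at -0.49 ± 1.13. Cell cycle genes were higher in 17 of 20 cases (median 0.28, with Stmn1 at 0.88 ± 0.21 and Cdk1 at 0.65 ± 0.25). Their pair medians were 0.77 and 0.30 in gray matter at 4 and 8 weeks, but -0.07 and 0.11 in white matter. Their mean log2 CPM was 4.16 in CCH gray matter at 4 weeks and 3.02 to 3.47 in the other libraries. Nuclear oxidative phosphorylation genes were higher in 21 of 23 cases (median 0.13, with Uqcrq at 0.28 ± 0.10). Mitochondrially encoded transcripts were higher in 11 of 13 (median 0.28, with Mt-nd6 at 0.29 ± 0.12).

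Immediate early genes were lower in CCH in 23 of 25 cases (median -0.52; Fos -0.81 ± 0.37, Jun -0.47 ± 0.23) and inflammatory genes in 20 of 25 (median -0.30; the lipopolysaccharide co-receptor Cd14 -0.69 ± 0.24, Il1b -0.83 ± 0.87). Among 18 hypoxia genes 6 were higher and 12 lower (median -0.07, adjusted p = 0.271). Homeostatic genes had a median of -0.05 (adjusted p = 0.234), with P2ry12 at -0.26 ± 0.17 and Tmem119 at -0.15 ± 0.22, and 1 member, the sialic acid receptor Siglec5 (-1.03 ± 0.18), fell when adjusted over the list alone. The remaining lists did not pass. Their medians were 0.06 for lysosomal (adjusted p = 0.0571), 0.09 for MHC class I (0.287), -0.0085 for interferon (0.985), -0.08 for complement (0.234), 0.08 for cholesterol efflux (0.159), 0.05 for glycolysis (0.542), 0.07 for antioxidant (0.525), -0.01 for phagocytic (0.730), 0.10 for S100 (0.0907) and -0.06 for alternative activation genes (0.930). MHC class II genes had a median of -0.12 while camera's direction was up (0.857), and means differed in sign from medians for homeostatic (0.01) and phagocytic genes (0.02).

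Camera's adjusted p was 1.42e-04 for damage-associated, 2.62e-07 for cell cycle, 0.00105 for oxidative phosphorylation, 0.00123 for mitochondrially encoded, 1.89e-08 for immediate early and 0.00169 for inflammatory genes. With an estimated correlation all 6 calls were lost (adjusted p = 0.702 for oxidative phosphorylation and 0.623 for the other 5). The immediate early and inflammatory medians turned to 0.28 and 0.24 without the sham 4-week pool and to 0.23 and 0.20 without the CCH 4-week pool. In the same settings the oxidative phosphorylation median turned to -0.0055 and -0.0074 and the damage-associated call ended (0.04, adjusted p = 0.318, and 0.08, adjusted p = 0.228). Without the sham white matter library at 4 weeks the inflammatory (-0.08, adjusted p = 0.345) and oxidative phosphorylation calls (0.06, adjusted p = 0.175) ended, and the inflammatory call ended without the sham gray matter library at 8 weeks (-0.22, adjusted p = 0.0868). Without the CCH 8-week or the sham 8-week pool these calls held and medians were larger, at -1.26 and -1.24 for immediate early, -0.64 and -0.79 for inflammatory, 0.44 and 0.46 for damage-associated and 0.27 and 0.25 for oxidative phosphorylation genes. Without the sham gray matter library at 8 weeks the damage-associated and oxidative phosphorylation medians were 0.48 and 0.24, and without the sham white matter library at 4 weeks the immediate early median was -0.31. The mitochondrial call ended without the CCH 4-week pool (0.25, adjusted p = 0.210), the sham 4-week pool (0.22, adjusted p = 0.294) or the sham white matter library at 4 weeks (0.21, adjusted p = 0.331). With the immediate early level of each library as a covariate, the inflammatory median turned to 0.09 (adjusted p = 0.704).

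Of 12403 genes none passed between CCH and sham (smallest adjusted p = 0.752, edgeR), with 564 at an unadjusted p under 0.05, 263 higher and 301 lower. DESeq2 called 37. By the naming rule, the genes with the smallest p that were higher in CCH in 4 of 4 pairs were Cd99 (0.66 ± 0.13), the endoplasmic reticulum degradation factor Edem1 (0.43 ± 0.09), Icam5 (0.39 ± 0.09), the glycosyltransferase C1galt1 (0.52 ± 0.12) and Hypk (0.45 ± 0.11). Those lower were Sqle, Siglec5, the antizyme inhibitor Azin1 (-0.69 ± 0.13), the UDP-glucose receptor P2ry14 (-0.45 ± 0.09) and Cyp51. Cd74, which assembles MHC class II, stood at -0.42 ± 1.37, and without the sham gray matter library at 8 weeks it stood at 1.01. The count of 0 became 11 without that library, 264 without the whole sham 8-week pool and 35 without the CCH 8-week pool.

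Within one region and time the comparison of CCH with sham had 1 library a side and no test, so values are given with exact Poisson 95% intervals that cover counting error only. In white matter at 4 weeks, Gpnmb, a lysosomal glycoprotein, stood at 162 CPM (159 to 166) in CCH and 4.47 (3.89 to 5.10) in sham microglia, and at 8 weeks at 41.6 (39.8 to 43.5) and 9.34 (8.42 to 10.3). In gray matter it stood at 2.59 and 2.46 CPM at 4 weeks and at 1.48 and 2.29 at 8 weeks. Lgals3, which encodes galectin-3, followed at 39.8 (38.0 to 41.6) against 1.87 CPM in white matter at 4 weeks and 9.64 against 4.16 at 8 weeks, and Clec7a, a glucan receptor, at 25.7 against 3.64 and 9.04 against 2.38. Axl, a receptor tyrosine kinase for apoptotic cells, stood at 45.8 against 10.2 and 23.5 against 12 CPM in white matter, and in gray matter at 8 weeks at 1.87 in CCH and 25.5 in sham microglia. Spp1 was high in both regions at 4 weeks, at 83.5 CPM in gray and 104 in white matter of CCH against 5.22 and 19.2 in sham rats. Lymphocyte-like cells of the CCH white matter libraries, which should lack Gpnmb, held it at 31.1 CPM at 4 weeks and 242 at 8 weeks, where 127 of 184 UMIs came from 1 cell. Without that cell the 8-week value was 78.4 CPM (59.4 to 102), still above the 41.6 CPM of microglia in that library.

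**Figure D2:**
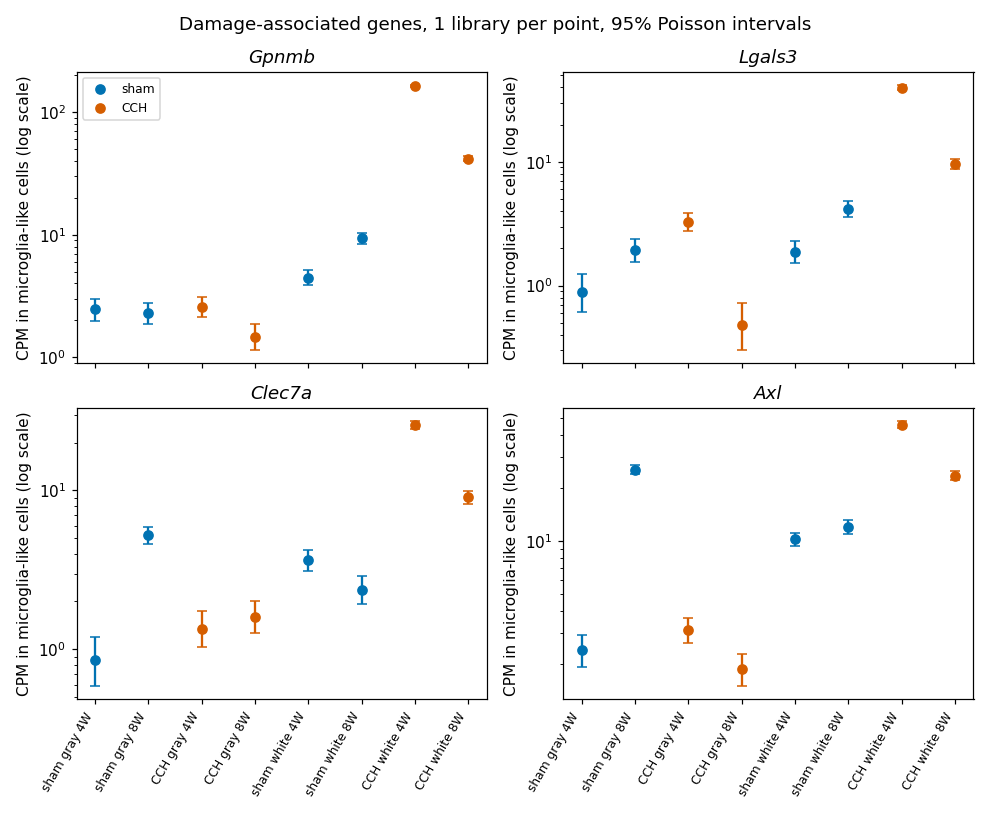
Levels of Gpnmb, Lgals3, Clec7a and Axl in microglia-like cells (vertical axis, CPM on a log scale), 1 point per library with exact Poisson 95% intervals. The CCH white matter libraries at 4 and 8 weeks hold the highest values for Gpnmb (162 and 41.6), Lgals3 and Clec7a, while for Axl the sham gray matter library at 8 weeks (25.5) lies above CCH white matter at 8 weeks (23.5).

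The third comparison set 8 weeks against 4 weeks and cannot separate time after surgery from age or processing day. Mpped2 (ENSRNOG00000004863), a metallophosphoesterase, was the 1 gene that passed and fell by 0.99 ± 0.09 on the log2 scale (adjusted p = 0.0353, edgeR, lower in 4 of 4 pairs). It stood at 13 to 17.4 CPM at 4 weeks and 7.02 to 8.59 at 8 weeks, and as its mean lies below 20 CPM it was chosen after its values were seen. Among genes of the naming rule, none of which passed, higher values at 8 weeks belonged to the chaperone organizer Stip1 (0.94 ± 0.11) and the endoplasmic reticulum stress gene Creld2 (0.76 ± 0.10), both at adjusted p = 0.0622, Banp (0.67 ± 0.09, adjusted p = 0.0702), the angiopoietin receptor Tek (0.63 ± 0.10) and Trak2 (0.46 ± 0.07). Lower values belonged to the actin-capping protein Capg (-0.66 ± 0.09, adjusted p = 0.0622), thromboxane synthase Tbxas1 (-0.71 ± 0.10, adjusted p = 0.0702), Nmd3 (-0.57 ± 0.09), Med29 (-0.61 ± 0.10) and peroxiredoxin Prdx1 (-0.66 ± 0.11, adjusted p = 0.0946). Spp1 stood at -3.38 ± 0.77 (adjusted p = 0.254).

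The gene lists were tested for time only after the data were seen. Cell cycle genes were lower at 8 weeks in 19 of 20 cases (median -0.32, with Stmn1 at -0.74 ± 0.21 and Mcm2 at -0.47 ± 0.14). Their pair medians were -0.28 in sham gray, -0.16 in sham white, -0.83 in CCH gray and 0.10 in CCH white matter. Glycolysis genes were lower in 12 of 15 (median -0.22; Tpi1 -0.67 ± 0.16) and nuclear oxidative phosphorylation genes in 23 of 23 (median -0.14; Atp5mc3 -0.39 ± 0.15), while hypoxia genes were higher in 16 of 18 (median 0.09; prolyl hydroxylase P4ha1 0.79 ± 0.14) and mitochondrially encoded transcripts in 12 of 13 (median 0.15; Mt-nd5 0.67 ± 0.15). Camera's adjusted p was 2.69e-05, 0.00462, 0.00746, 0.0399 and 0.0483 in that order, and with an estimated correlation all 5 calls were lost (adjusted p from 0.701 to 0.885). The oxidative phosphorylation and glycolysis calls ended without the CCH 4-week pool (0.01 and -0.08, adjusted p = 0.943 and 0.175) and without the CCH 8-week pool (-0.01 and -0.11, adjusted p = 0.997 and 0.173). The hypoxia call ended without the CCH 4-week pool (0.16, adjusted p = 0.175), the CCH 8-week pool (0.10, adjusted p = 0.219), the sham 4-week pool (0.10, adjusted p = 0.103) or the sham white matter library at 4 weeks (0.07, adjusted p = 0.119). The mitochondrial call ended without the CCH 4-week pool (0.23, adjusted p = 0.0569), the sham 4-week pool (0.15, adjusted p = 0.213), the sham 8-week pool (0.14, adjusted p = 0.313), the sham gray matter library at 8 weeks (0.03, adjusted p = 0.464) or the sham white matter library at 4 weeks (0.0034, adjusted p = 0.414). Oxidative phosphorylation medians were -0.27 without either sham pool and -0.24 without the sham gray matter library at 8 weeks. At an unadjusted p under 0.05 stood 1607 genes, 787 higher and 820 lower. Mpped2 was the only call by edgeR, but DESeq2 called 176 genes, the fit without the sham 8-week pool 149, without the sham gray matter library at 8 weeks 62, and without either 4-week pool 0.

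The other lists did not pass for time. Medians were 0.09 for homeostatic (adjusted p = 0.339), -0.11 for damage-associated (0.197), 0.03 for lysosomal (0.559), 1.17 for MHC class II (0.410), -0.06 for MHC class I (0.366), 0.02 for interferon (0.813), 0.04 for inflammatory (0.813), -0.02 for cholesterol efflux (0.784) and 0.08 for cholesterol synthesis genes (0.410). They were -0.02 for antioxidant (0.454), -0.08 for phagocytic (0.454), -0.09 for S100 (0.410) and 0.20 for alternative activation genes (0.752). Pair medians of MHC class II genes were 4.01 in sham gray and 0.45 in sham white matter, but -0.51 in CCH gray and -0.30 in CCH white matter. Immediate early genes had a median of -0.03 and a mean of 0.16 (0.233), and complement genes a median of -0.04 and a mean of 0.04 (0.752). Adjusted over the list alone, the chaperone Hspa1b (0.69 ± 0.15), the integrin Itgam (0.56 ± 0.10) and superoxide dismutase Sod1 (0.38 ± 0.09) rose and Prdx1 fell. Among mitochondrially encoded transcripts, which passed as a list, Mt-nd5 rose and Mt-nd6 fell by the same adjustment.

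The fourth comparison asked whether the white minus gray difference was larger in CCH than in sham rats. No gene of 12403 passed (edgeR, smallest adjusted p = 0.367, for Lgals3), with 1337 at an unadjusted p under 0.05, 708 higher and 629 lower, and DESeq2 called 31. Damage-associated genes had positive interaction terms in 17 of 21 cases (median 0.57): Lgals3 at 3.04 ± 0.31, Gpnmb at 4.21 ± 0.55, Cd63 at 0.95 ± 0.22, Apoe at 0.75 ± 0.24 and Trem2 at 0.57 ± 0.23. The first 3 rose when adjusted over the list alone. Other genes of the naming rule with positive terms were the MHC class I gene RT1-T24-3 (1.01 ± 0.17), the adaptor Hcst (1.16 ± 0.22) and Hist1h1c (0.85 ± 0.17). Those with negative terms were cyclin Ccnd2 (-0.95 ± 0.13), Crim1 (-0.92 ± 0.13), the growth factor Hbegf (-1.37 ± 0.19), Dhrs9 (-1.28 ± 0.19) and Tagln2 (-0.77 ± 0.13), all at adjusted p = 0.452.

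Lists tested for the interaction after the data were seen followed. Positive terms belonged to 19 of 20 lysosomal genes (median 0.31), 7 of 8 MHC class II genes (2.37; RT1-Bb 4.13 ± 1.78, Cd74 2.33 ± 2.03), 14 of 14 MHC class I genes (0.61), 22 of 30 interferon genes (0.46), 10 of 15 cholesterol efflux genes (0.37; Apoc1 1.59 ± 0.37, Abcg1 0.77 ± 0.17), 23 of 23 nuclear oxidative phosphorylation genes (0.41; Uqcrh 0.72 ± 0.21) and 12 of 13 mitochondrially encoded transcripts (0.83; Mt-atp6 1.39 ± 0.31, Mt-co1 1.10 ± 0.28). Adjusted over the list alone, 10 genes rose in each of the last 2 lists. Cell cycle genes had negative terms in 16 of 20 cases (median -0.30), and cholesterol synthesis genes had a median of 0.0092 (adjusted p = 0.831, camera). That median near 0 depends on TMM scaling. From CPM without it, white minus gray pair medians of cholesterol synthesis genes at 4 and 8 weeks were 0.69 and 0.70 in sham and 0.47 and 0.38 in CCH rats. Median mitochondrial UMI shares of kept cells, which move with the mitochondrial list, were 2.88% and 3.13% in sham white matter at 4 and 8 weeks and 3.94% to 5.39% in the other 6 libraries.

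Camera's adjusted p was 7.19e-10 for damage-associated, 0.0059 for lysosomal, 0.0219 for MHC class II, 4.91e-05 for MHC class I, 0.00259 for interferon, 0.0219 for cholesterol efflux, 7.19e-10 for oxidative phosphorylation, 7.69e-11 for mitochondrially encoded and 0.0132 for cell cycle genes. With an estimated correlation no call held (adjusted p from 0.674 to 0.858). Without the sham 8-week pool the calls of MHC class II (median 0.22, adjusted p = 0.203), MHC class I (0.17, adjusted p = 0.203), cholesterol efflux (0.11, adjusted p = 0.174), interferon (-0.04, adjusted p = 0.527) and cell cycle genes (-0.33, adjusted p = 0.158) ended. Without the CCH 4-week pool those of lysosomal (0.19, adjusted p = 0.360), cholesterol efflux (0.17, adjusted p = 0.238) and cell cycle genes (0.0013, adjusted p = 0.658) ended, and without the sham 4-week pool those of lysosomal (0.28, adjusted p = 0.111) and cell cycle genes (-0.40, adjusted p = 0.0698). Without the sham 4-week pool the medians of MHC class II (4.58), MHC class I (1.25) and interferon genes (1.40) were larger, as was that of interferon genes without the CCH 4-week pool (0.70), and without the CCH 8-week pool the cell cycle median was -0.85. Scaling by library size alone moved the median interaction of all genes by -0.24, and medians then were 0.07 for lysosomal, 0.18 for oxidative phosphorylation, 0.33 for damage-associated, 0.37 for MHC class I, 0.22 for interferon and 0.13 for cholesterol efflux genes, with the cell cycle call ended (-0.53, adjusted p = 0.0524). The count of 0 genes became 670 without the sham 4-week pool and 26 without the sham 8-week pool.

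The other lists did not pass for the interaction. Medians were -0.11 for homeostatic (adjusted p = 0.343), 0.29 for immediate early (0.0553), 0.21 for complement (0.536), 0.14 for hypoxia (0.668), 0.03 for glycolysis (0.768), 0.14 for antioxidant (0.668) and 0.14 for phagocytic genes (0.294). Inflammatory genes had a median of 0.10 while camera's direction was down (0.797), with the chemokine Ccl7 at -2.27 ± 0.39, which fell when adjusted over the list alone. S100 genes had a median of 0.28 and a mean of -0.26 (0.668), and alternative activation genes had a median of 0.08 while camera's direction was down (0.797), with the growth factor Pdgfa at -0.89 ± 0.16.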

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

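Of the tests in this part, those of free RNA, handling and oligodendrocyte RNA were written before their values were computed, and all others were chosen after the result was seen.

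Among 44 sets of 4 libraries (the levels of fixed genes and of part of the 20 lists within CCH or sham) examined for a library far from the others, 2 stood out, with 2.2 to be had by chance at 1 in 20. The complement list was not among these sets. Its mean log2 CPM was 7.66 in sham gray matter at 8 weeks and 7.25 to 7.30 in the other sham libraries. Inflammatory genes had a mean log2 CPM of 6.24 in CCH white matter at 8 weeks and 5.40 to 5.53 in the other 3 CCH libraries, while sham white matter at 4 weeks, outside that comparison, had 6.54. Trem2, a lipid-sensing receptor, had a log2 CPM of 10.7 in sham gray matter at 4 weeks and 10.1 to 10.2 in the other 3 sham libraries. A further 9 lists stood out because the white minus gray difference was not the same in CCH and sham rats: damage-associated (0.57), lysosomal (0.31), MHC class II (2.37), MHC class I (0.61), interferon (0.46), cholesterol efflux (0.37), nuclear oxidative phosphorylation (0.41), cell cycle (-0.30) and mitochondrially encoded genes (0.83). With an estimated correlation none of the 9 passed (adjusted p from 0.674 to 0.858), and without the sham 8-week pool 5 did not, MHC class II (0.22), MHC class I (0.17), cholesterol efflux (0.11), interferon (-0.04) and cell cycle genes (-0.33). Without the CCH 4-week pool lysosomal (0.19), cholesterol efflux (0.17) and cell cycle genes (0.0013) did not pass, nor without the sham 4-week pool lysosomal (0.28) and cell cycle genes (-0.40), nor cell cycle genes with library size alone (-0.53).

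Damage-associated genes, led by Gpnmb and Lgals3, were high in microglia of both CCH white matter libraries. Free RNA in the droplets was excluded as the whole cause: cells with a Gpnmb UMI held 2.20 times (lower quartile 1.36) the CPM of the other members at 4 weeks and 1.61 times (1.25) at 8 weeks, against 1.02 and 1.03 for 243 abundant genes. Border macrophages or monocytes counted as microglia would, by their markers, bring up to 0.980% of the Gpnmb level over 4 pairs of class and library. That value was 0.348% over 3 pairs before the marker minimum was lowered from 100 to 50 CPM after the values were seen. The estimate rests on 11 to 16 cells per class and library, and on 3 markers for monocytes. It does not cover such cells that had lost these markers, and these were not tested. Against the exclusion of free RNA, the share of cells with a Gpnmb UMI, thinned to 2000 UMIs, was no higher in microglia than in lymphocyte-like cells. At 4 weeks the shares were 6.99% and 7.50% (exact binomial interval of the latter 3.49 to 13.8), at median depths of 5151.5 and 4848.5. At 8 weeks they were 2.29% and 7.77% (3.41 to 14.7), at 5415 and 4231. Microglial Gpnmb UMIs lay in 998 cells at 4 weeks, against 4148 expected if spread evenly, and in 394 against 1615 at 8 weeks. Those of lymphocyte-like cells lay in 17 against 21.6 at 4 weeks and in 10 against 73.4 at 8 weeks. Only the lymphocyte-like cells at 4 weeks thus came near an even spread, and free RNA may add part of the Gpnmb level. Whether the pattern would recur in other rats stays open, since each library was 1 pool.

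Cholesterol synthesis genes, among them Sqle and Cyp51, were higher in white matter and lower in CCH, calls lost with an estimated correlation (adjusted p = 0.14 and 0.244). A response to handling was excluded for these genes only as far as the immediate early level of a library measures it. With that level as a covariate, at camera's preset correlation, the medians were 0.48 (adjusted p = 4.29e-16) for region and -0.36 (adjusted p = 1.14e-16) for condition. Inflammatory genes went from 0.57 to -0.05 (adjusted p = 0.869) and from -0.30 to 0.09 (adjusted p = 0.704). The region call of damage-associated genes ended (adjusted p = 0.302, with 1 residual degree of freedom fewer). Their median was 0.10 (quartiles -0.17 to 1.74) before and 0.35 (quartiles -0.15 to 0.68) after. Handling effects that do not move with the immediate early level were not tested. For region, oligodendrocyte RNA was excluded as the main source only at the median share that 11 oligodendrocyte markers allow, 0.0941% of microglial UMIs. At that share it would bring a median of 0.888% (upper quartile 1.14%) of the white minus gray difference, from 50 oligodendrocyte-like cells. A single marker allowed up to 6.43%, far above the median marker, and the part brought at that share was not computed. Chance in how libraries fell into groups was not excluded for condition, where 5 of 35 splits, the real one among them, gave a median as far from 0 (real -0.33, highest other 0.476, in the split of gray against white matter), while of the 8 splits within pairs matched by region and time, too few for a share under 0.05, only the real one did (highest other 0.268). For region only the real split did so, 1 of 8 that part every pool (real 0.47, highest other 0.294), and 8 are too few for a share under 0.05; over all 35 splits, tried first, it was 11 with the real one (highest other 0.578).

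Some genes were near 0 in 1 library of an 8-week pool and not in the other, such as Fam111a at 1.73 CPM in sham white and 71.5 in sham gray matter. Exchanged gray matter libraries stay open, as re-pairing parted the libraries by 15 genes against 10 as labelled, and a first version of that test, which asked only for as many genes, would have excluded it. Against an exchange, LOC685048 was low in both CCH libraries at 8 weeks (2.50 and 1.35 CPM, and 32.0 and 29.4 in sham), as was Lilrb3a (2.62 and 2.45, and 13.8 and 53.6), and cluster 7 held 2025 and 2507 cells of the CCH and 12 and 134 of the sham libraries at 8 weeks, but these genes and this cluster were picked after their values were seen and deviations from region means correlated best across conditions. Different rats in the 2 libraries of a pool stay open too, with 5 such genes in the less parted 8-week pool and 2 to 12 (median 5) between pools. Inherited differences between outbred rats could set such genes, and this was not tested.

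Counts of genes were set against other splits of the libraries, the real split included each time. For region 2 of 8 splits called as many genes (real 3, highest other 10, in the split that exchanges gray and white matter of the sham 8-week pool), where 8 are too few for a share under 0.05, and 7 of the 35 splits tried first did so. For condition the real count was 0, so that 35 of 35 splits reach it whatever the data, and the comparison decides nothing (highest other 8). For time 6 of 35 called as many (real 1, highest other 5), and chance was not excluded.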

How the results depend on the processing

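Alternatives without either single sham library, with the top 5% of doublet scores removed and with no pool block for the lists were chosen after seeing the data. Counts of genes moved widely with the processing, and the cause was not tested. The region count of 3 genes was 147 with DESeq2, 61 without a low-count filter, 109 with all cells summed, 0 with no pool block and 0 to 174 with 1 pool left out. The condition count of 0 was 37 with DESeq2, 1 with pool sums, 1 in white libraries alone and 0 to 264 with 1 pool or library left out. The time count of 1 was 176 with DESeq2, 0 with library size alone, 24 without a filter, 0 with all cells summed, 2 with pool sums, 19 with voom, 0 in gray and 2 in white libraries alone and 0 to 149 with 1 pool or library left out. The interaction count of 0 was 31 with DESeq2, 6 without a filter and 0 to 670 with 1 pool left out. Lists passing were 8 for region (8 to 9 with 1 pool left out), 7 for condition (3 to 11), 5 for time (4 to 11) and 9 for the interaction (6 to 12), and 0 in each with an estimated correlation. The white minus gray difference in microglia-like cells ran from 6.34 to 7.36 points, higher in 4 of 4 pairs except with the laxer filter (6.56, 3 of 4, exact p = 0.25). CCH minus sham, 1.04 points, was 0.353 at Leiden resolution 0.5 (2 of 4 pairs, exact p = 0.875) and 2.52 with the laxer filter.

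Of 1515 values of named genes 1372 were the same, 102 stronger, 18 weaker and 23 reversed, and of 206 list medians 135 were the same, 61 weaker and 10 reversed. Here the same means the same sign and the same call, whatever the size, stronger a call gained and weaker a call lost. Most named genes did not pass in the main fits, so for them the same means only an unchanged sign and still no call. Sizes could move, as for Spp1 over time, from -5.14 to -2.29. Only lists that passed are counted, a cut made after the values were seen, and medians of other lists changed sign in many settings. With all cells summed the region values of Cxcl1, Cd74 and Lpl were -0.87, -0.49 and -0.52. In gray libraries alone the condition values of P2ry12, Tmem119, Lpl and Trem2 were 0.018, 0.0048, 0.53 and -0.0084, and in white libraries alone Cd74 was 0.97. With 1 pool or library left out, region values ran from -0.81 to 1.04 for Lpl, -0.27 to 0.0073 for Trem2, -0.090 to 0.27 for P2ry12 and -0.37 to 0.075 for the interferon list. Condition values ran from -0.63 to 0.33 for Tmem119, -1.94 to 0.57 for Il1b, -2.19 to 1.19 for Cd74, -3.00 to 1.23 for Lpl, -1.65 to 0.039 for Fos, -0.95 to 0.019 for Jun, -0.79 to 0.24 for the inflammatory, -1.26 to 0.28 for the immediate early and -0.0074 to 0.27 for the oxidative phosphorylation list. The time range of the oxidative phosphorylation list was -0.27 to 0.011, and interaction ranges were -0.85 to 0.0013 for cell cycle and -0.044 to 1.40 for interferon genes. The sterol medians kept direction and call in every setting with the preset correlation (0.46 to 0.55 for region, -0.36 to -0.18 for condition, lowest in size without the CCH 8-week pool). No paired analysis was possible because each group held 1 library, all numbered 1; this concerns pairing by replicate number, and the pool block and the 4 pairs used here instead match libraries by condition, region and time. Depth limited genes below 0.0618 to 0.0776 CPM.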

Other observations

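Genes of this part, apart from Cd74 and Siglec5, were picked after their values were seen, and values of single libraries have no test. In the sham gray matter library at 8 weeks, Cd74, which assembles MHC class II, stood at 6607 CPM in its microglia and at 289 to 2092 in the others, and RT1-Ba, a class II chain, at 1768 and 44.0 to 588. The same library held 452 lymphocyte-like cells (6.25%) and 611 border macrophage-like cells (8.45%). Siglec5 stood at 252 CPM in it, 444 in sham white matter at 8 weeks, 236 and 214 in sham gray and white matter at 4 weeks and 107 to 180 in the 4 CCH libraries.

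In CCH white matter at 8 weeks the clock gene Per3 stood at 126 CPM and the clock output factor Dbp at 65.1, against 26.5 to 49.3 and 8.03 to 17.4 in the other libraries. The neutrophil calprotectin genes S100a8 and S100a9 stood at 62.1 and 69.6 CPM in microglia-like cells of sham white matter at 4 weeks, against 0.776 to 4.89 and 1.01 to 7.09 elsewhere. Both genes also led an unnamed cluster of 193 cells with neutrophil markers, 18 of them from that library. Whether RNA of such cells set these microglial values was not tested. Interferon genes such as Mx1, Cxcl10 and Ifit3 led a cluster of 470 cells, and Mki67 and Top2a led a cycling cluster of 313 cells.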
